A study of Homo sapiens with 2 samples.

How the data were processed

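The data came from MCF7, an established human breast cancer cell line that expresses the oestrogen receptor α (ERα). Per the labels, the cells were starved of serum for 72 h and treated with oestradiol (E2), the natural ligand of the receptor, for 45 min. They were then fixed with 1% formaldehyde for 10 min. Chromatin immunoprecipitation with sequencing (ChIP-seq) used the ERα antibody H-20. There were 2 samples with 1 library each, an ERα immunoprecipitation and an input DNA control. Peaks of the immunoprecipitated library were analysed. The reads of both libraries and the input as a measurement of its own were not analysed here, so the depth behind each peak is unknown. Samples treated with an inhibitor of group II p21-activated kinases (PAKs), the subject of the series, were not analysed here.

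The deposited file was a peak list with a position, a name and a score for each peak. Per the submitters' processing notes the reads were handled with CASAVA 1.8, aligned with Bowtie 0.12.9 and placed on hg19. The peak names begin with MACS, a peak caller. Its version, its control and its cut-off are not given in the sources used here. The name of the peak list pairs ERα with Input, but whether the input library served as the control is not stated. The score is the authors' value for each peak. Its minimum was exactly 50, and its scale looks like that of a transformed p-value, but the sources used here do not state it. The score served only to rank and describe peaks within this list.

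Positions were read against the GRCh37 primary assembly, whose chromosome lengths equal those of hg19, and against GENCODE release 44 mapped to GRCh37. Peaks on chromosomes 1 to 22, X and Y entered every comparison. Peaks on other sequences were counted apart. 3 peaks began before position 1 and were shortened to the chromosome. A peak was placed by its midpoint. Signed distances to a transcription start site (TSS) are negative upstream and positive downstream on the strand of the gene. The feature under a midpoint was the first that applied of promoter (within 1 kb of a protein-coding TSS), 5′ untranslated region (UTR), coding exon, 3′ UTR, other exon, intron and intergenic.

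Peaks near a TSS (within 5 kb), features and clustering (another peak starting within 10 kb) were compared with 1000 random placements that kept each peak's chromosome and width and avoided assembly gaps. The range from the lowest to the highest 2.5% of the placements is given as the 95% range. Chromosome density was peaks per megabase (Mb) of sequence without N. Each chromosome's share was tested against its share of that length with a two-sided exact binomial test, adjusted by the Benjamini-Hochberg method over 24 chromosomes. Motifs were searched on both strands in each peak and in a pair of flanks of equal width that began 2 kb outside it. In the full list, comparisons with flanks covered the 17986 peaks with no N in the peak or its flanks. The central 200 bp left 17996 peaks and flanks 10 kb away left 17919. Motif comparisons without flanks, such as those by score, used all 18040 peaks. The oestrogen response element (ERE), the palindrome the receptor recognises, was GGTCANNNTGACC with at most 1 mismatch among its 10 fixed bases. Control palindromes had a spacer of 2 or 4 bases or rearranged bases. Peaks were compared with their upstream flank by a two-sided exact McNemar test, adjusted over 17 motifs. Intervals of motif ratios to flanks came from 1000 bootstrap resamples of peaks, and those of shares were exact binomial. In the closing sections, ratios between groups of peaks used 2000 bootstrap resamples, and motif ratios at matched width used fewer. The interval of the ERE ratio of chromosome Y was an exact binomial one divided by the autosomal share. The 20% of peaks with the highest scores were compared with the 20% with the lowest by a two-sided Fisher's exact test, and across peaks Spearman's rho was tested with 100000 permutations.

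For 14 gene lists, the members with a peak midpoint within 50 kb of a protein-coding TSS were counted. Each count was compared with 10000 random lists of the same size, matched on gene length in 10 classes and on the number of neighbouring TSSs within 50 kb in 5 classes. The two-sided p of this permutation of list membership came from the percentile and was adjusted over the 14 lists. Of 253 listed members, 251 were found under the listed symbol, MYLPF was found as MYL11, and CD24 was not found. The lists were oestrogen-induced genes, luminal transcription factors, luminal epithelial structure, nuclear receptor coregulators, PAKs, growth factor and survival signalling, cell cycle, immediate early genes, housekeeping genes, basal and mesenchymal genes, skeletal muscle genes, neuronal genes, hepatocyte genes and leukocyte genes. Some genes were in more than 1 list.

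Lists, tests, motifs and the rule for named genes were fixed before the data were examined. The rule named the members of the oestrogen-induced, luminal transcription factor and PAK lists, with values for those with the highest-scoring peaks and for all without a peak. It also named the 10 highest-scoring peaks, the 10 genes with the most peaks within 50 kb, and the 2 members of every other list with the highest-scoring peak. Genes named outside the rule are marked as chosen after their values were seen.

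Peaks with another copy in the genome were found by aligning peak sequences with minimap2 2.31-r1302 and keeping alignments of at least 90% identity over at least 80% of the peak. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The alternatives were a higher score threshold, other windows, overlaps and distances, other motif settings and backgrounds, merging of adjacent peaks, whole chromosome lengths and unmatched random lists. The methods were tested on simulated data, with positions left unchanged, positions moved to a TSS, planted EREs and gene lists with a known excess of peaks. Unchanged positions gave mean ratios of 0.988 to 1.03, and positions moved to a TSS gave 2.80 where 2.78 was made.

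No replicates were present, so no spread between replicates could be measured. Intervals and p-values describe this list of peaks and cover counting error only. Neighbouring peaks are not independent, which makes the binomial and McNemar p-values too small. Listed genes that are neighbours can share a peak, while random lists drew genes independently within their classes. The permutation p-values of lists with such neighbours may therefore also be too small.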

Results

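ERα binding in E2-treated MCF7 cells was described by 18236 peaks, of which 18040 (98.9%) lay on chromosomes 1 to 22, X and Y. These covered 8.48 Mb, 0.297% of the sequence without N. The median width was 377 bp (interquartile range 286 to 523 bp) and the median score was 80.1 (interquartile range 58.5 to 188). Scores reached 3233, with 7368 peaks (40.8%) at 100 or more and 1010 (5.60%) at 1000 or more. A score of exactly 3100 was shared by 73 peaks and exceeded by 10. A value repeated this often looks like a limit of the scale. Whether the 10 peaks above it are stronger than the 73 at it can therefore not be told.

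Genes known to be induced by oestrogen lay near ERα peaks more often than matched genes. Of 45 such genes, 44 had a peak within 50 kb of a TSS, against a mean of 22.9 in random lists (95% range 16 to 29), a ratio of 1.92. The highest-scoring peak near the gene scored 1000 or more for 31 of the 44. TFF1 (ENSG00000160182), a secreted trefoil protein and a classical oestrogen-responsive gene, had 14 peaks. Its highest-scoring peak (chromosome 21, 43785860 to 43787262, score 3100) covered the promoter and carried an ERE. GREB1, a cofactor of the receptor, had 11 peaks, and the highest-scoring one (chromosome 2, 11670906 to 11671561, score 2315) was intronic, at −2.9 kb from the nearest TSS. In the permutation test against random lists, the two-sided p was 0.0002, the smallest that the 10000 lists can give, and the adjusted p was 0.0014. The ratio was 3.06 with peaks at or above the median score and 4.20 within 10 kb.

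Other members of the oestrogen-induced list had high-scoring peaks, mostly away from promoters. Near SIAH2, a ubiquitin ligase, the highest score was 3233, near the receptor tyrosine kinase RET 3104, and near ADCY9, an adenylate cyclase, 3100. The highest peak scored 2978 near PDZK1 (at the promoter), 2861 near P2RY2, 2795 near EGR3 and 2786 near HSPB8. Near XBP1, a transcription factor of the unfolded protein response, it scored 2686, near the retinoic acid receptor RARA 2670 and near the G1 cyclin CCND1 2588. For WWC1, CELSR2, the lysosomal protease CTSD, the keratins KRT13 and KRT19, and the apoptosis inhibitor BCL2, it scored 2661, 2619, 2383, 2357 and 2202. KRT13 and KRT19 shared that peak. An ERE was present in the highest-scoring peak of 15 of the 44 genes. The highest-scoring peak was at a promoter for 6 of the 44, and of these the peak of TFF1 carried an ERE.

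Some well-known members had peaks with lower scores than these. The progesterone receptor gene PGR had 2 peaks, the higher of which scored 70.4, lay 48.4 kb from the TSS and carried an ERE. The chemokine gene CXCL12 had 1 peak, with a score of 68.6. Neither gene kept a peak when peaks under the median score were left out. MYC had 1 peak, with a score of 102 and an ERE, 14.6 kb from the TSS. MYBL1 was the member of the list without a peak within 50 kb, and had 4 within 100 kb.

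Luminal transcription factor genes, which mark the epithelial lineage of these cells, also lay near peaks, 16 of 17 against a mean of 8.21 in random lists (95% range 4 to 12). The ratio was 1.95 (adjusted permutation p = 0.0014, from the smallest p the random lists can give). GRHL2, a grainyhead factor of epithelia, had 9 peaks with scores of up to 1823, and ELF3 had 7 with up to 835. ESR1, the gene of the receptor itself, had 5 peaks, the highest of which (chromosome 6, 151979143 to 151979589, score 408) carried an ERE at −32.3 kb. FOXA1, a forkhead pioneer factor, had 4 peaks, the highest at its promoter with a score of 254. GATA3 had 2 peaks with scores of up to 111, and TBX3 had none within 50 kb. XBP1 is a member of both this and the oestrogen-induced list. With a window of 100 kb the ratio was 1.41 and the adjusted permutation p was 0.137.

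Among the PAKs, the kinase family that the series concerns, PAK4 (ENSG00000130669, chromosome 19, 39616410 to 39673456) had 11 peaks within 50 kb of a TSS. The highest-scoring one (39641395 to 39642263, score 2874) was intronic, at −5.5 kb from the nearest TSS. Another intronic peak (39620567 to 39621489, score 2701) lay 4.6 kb downstream of a TSS, and a weaker one (39624894 to 39625410, score 270) lay 8.7 kb downstream. All 3 carried an ERE. PAK1 had 2 peaks with scores of up to 213 (chromosome 11, 77118740 to 77119036, intronic), and PAK2 had 2 with up to 98.5. PAK3, PAK5 and PAK6 had no peak within 50 kb, and PAK6 had 2 within 100 kb. The list as a whole had 3 of 6 members with a peak, 0.913 times the mean of random lists (adjusted permutation p = 1), so no difference from matched genes was detectable with 6 genes.

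**Figure D1:**
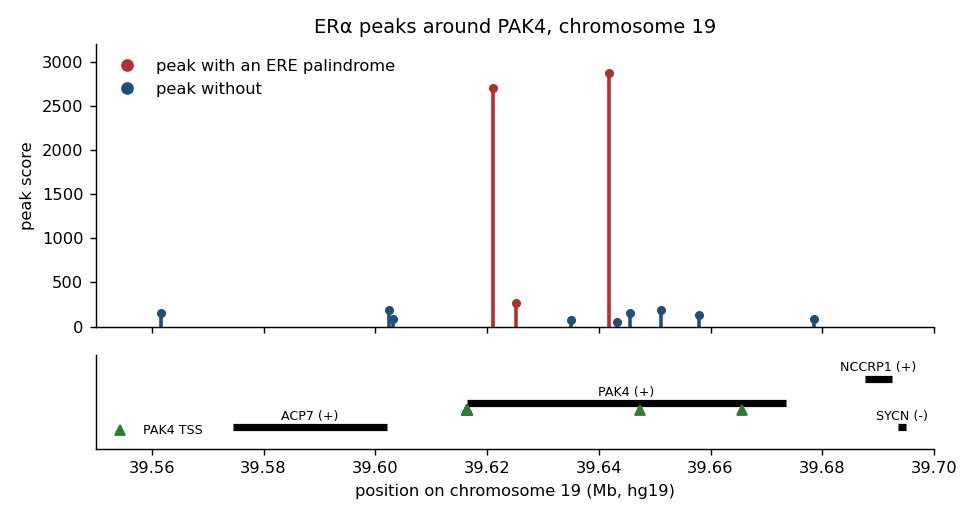
ERα peaks around PAK4 on chromosome 19 (hg19 position in Mb on the horizontal axis, peak score on the vertical axis), with the annotated genes and TSSs drawn beneath and peaks with an ERE marked. The peaks scoring 2874 and 2701 lie in introns of PAK4.

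Within 50 kb, none of the other 11 lists passed the test against matched genes, with adjusted permutation p-values from 0.437 (cell cycle genes) to 1. Luminal epithelial structure genes had a peak near 11 of 15 members (ratio 1.38), with the highest scores near KRT19 (2357) and KRT7 (2037). This list passed within 10 kb (2.72, adjusted permutation p = 0.0373) and with peaks at or above the median score (2.21, adjusted permutation p = 0.0121). Its neighbouring members KRT8 and KRT18 shared their highest-scoring peak, and KRT19 is also in the oestrogen-induced list. Cell cycle genes had one near 15 of 20 (1.39), led by CCND1 and CCND3 (1206). Immediate early genes had one near 10 of 15 (1.35), led by EGR3 and IER3 (1509). They passed within 10 kb (2.80, adjusted permutation p = 0.0406) and with the gene body and 10 kb (2.93, adjusted permutation p = 0.00747). FOS, EGR3 and MYC of this list are also in the oestrogen-induced list. Growth factor and survival genes had one near 13 of 20 (1.199), led by BCL2 and BCL2L1 (980.4), and coregulators near 11 of 20 (1.01), led by NRIP1 (1697) and NCOR2 (752).

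Lists of genes used in all cells or in other cell types gave ratios from 0.832 to 1.19. Housekeeping genes had a peak near 13 of 20 members (ratio 1.18), with TUBB (1509, the peak shared with IER3) and GUSB (872) the highest. Basal and mesenchymal genes had one near 11 of 18 (1.19), with ACTA2 (676) and KRT14 (510.4). Skeletal muscle genes had one near 9 of 18 (1.01), with MYOG (3100) and TNNI2 (2383, the peak shared with CTSD). The remaining lists were neuronal genes with 8 of 18 (0.832), hepatocyte genes with 8 of 16 (0.942) and leukocyte genes with 9 of 16 (1.046). Their highest scores were near GRIN1 (672) and GAD2 (469.7), APOA1 (1656) and SERPINA1 (848), and FCGR3A (695) and CD2 (176). Of all 19794 protein-coding genes, 10199 (51.5%) had a peak within 50 kb, so a single peak at this distance is a common event.

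**Figure D2:**
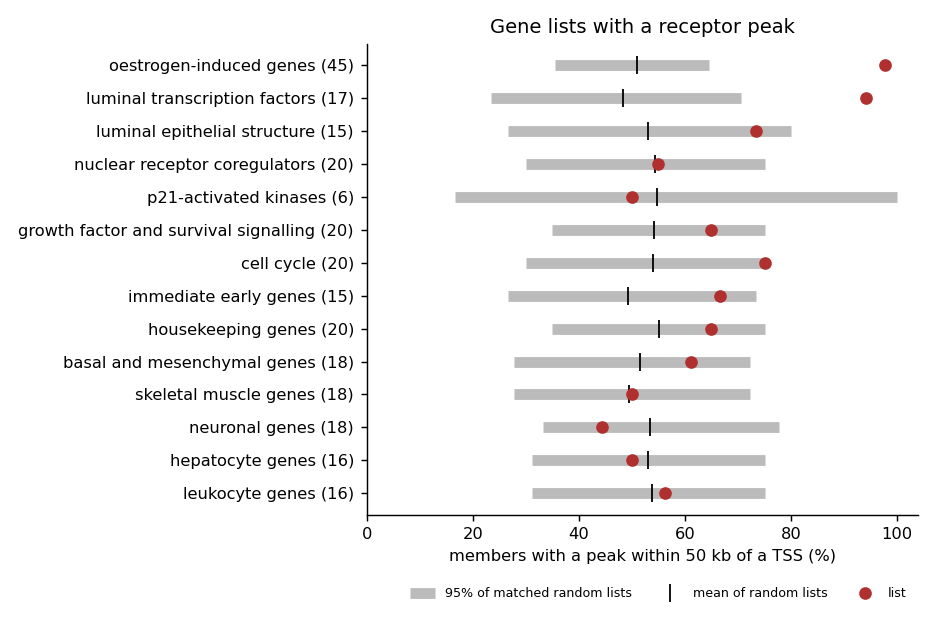
Share of members (percent, horizontal axis) with an ERα peak within 50 kb of a TSS for each of the 14 gene lists (points), beside the mean (ticks) and 95% range (bars) of matched random lists. The oestrogen-induced genes (44 of 45) and the luminal transcription factors (16 of 17) lie above their ranges.

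By the scores as given, the highest-scoring peak of the list lay on chromosome 3, from 150454870 to 150455611, in an exon 25.7 kb from the TSS of SIAH2. The next (chromosome 11, 69952128 to 69952934, score 3230.1) was in an intron 21 kb into ANO1, a chloride channel gene, and carried an ERE. The following peaks were an exonic one at −120.1 kb from NTMT1 (chromosome 9, 132250363 to 132251764, score 3200.5) and intronic ones near VWC2L (chromosome 2, 215242898 to 215243929, score 3168) and KLC1 (chromosome 14, 104159266 to 104160386, score 3158). Peaks near C19orf33 (chromosome 19, 38789342 to 38790446, score 3142) and GADD45B (chromosome 19, 2524852 to 2525585, score 3109) were intronic. An intergenic peak at 273.7 kb from the gene ENSG00000289710 (chromosome 1, 30775404 to 30776575, score 3132) carried an ERE. The peak near COL18A1 (chromosome 21, 46806093 to 46807260, score 3105) was intergenic with an exact ERE, and that of RET (chromosome 10, 43606000 to 43606956, score 3104) was intronic. Of these 10 peaks, 3 carried an ERE. The 73 peaks at exactly 3100 may be as strong as these 10 or stronger.

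Counted by number of peaks, CYP19A1, the gene of aromatase, stood first with 20 peaks within 50 kb, with scores of up to 111. Peaks were counted around every protein-coding TSS of a gene, so widely spaced TSSs can gather more of them. In the 1 Mb window with CYP19A1, chosen after its values were seen, the median width was 809 bp and 4.08% of peaks held an ERE. PREX1, a Rac exchange factor, had 19 with scores of up to 3064, and SHANK2 had 16 with up to 2742. CD22 and MAG, neighbours on chromosome 19, had 17 and 15 and shared their highest peak (35809798 to 35810412, score 3100, at the promoter of CD22). TFF2 had 17 and shared the highest peak of TFF1. ATXN7L1 had 15 (up to 3100), and LDLRAD4 and TNS3 had 14 each (up to 1986 and 1227).

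Of the 17 motifs, the ERE had the highest ratio of peaks to flanks. It was found in 2915 of 17986 peaks (16.2%) against 1.38% of flanks, a ratio of 11.7 (95% bootstrap interval 10.7 to 13). The ratio was 48.2 for exact matches, 2.84 with 2 mismatches and 23.9 in the central 200 bp. Control palindromes with a spacer of 2 or 4 bases gave 1.98 and 2.0, and the rearranged palindrome gave 1.38 (adjusted exact McNemar p = 0.000983). Of 3176 matches, 73.3% lay in the middle 33.3% of the length of their peak. The single arm AGGTCA of the palindrome was present in 55.4% of peaks against 29.7% of flanks (ratio 1.87).

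Sites of other transcription factors differed less between peaks and flanks, and in whole peaks of the full list all but RUNX passed the adjusted test. AP-1, the site of Fos and Jun proteins, was in 13.8% of peaks against 7.36% of flanks (ratio 1.88, adjusted exact McNemar p = 1.49e-97), AP-2 in 20.1% against 10.7% (1.88), and SP1 and KLF in 8.65% against 4.44% (1.95). The CTCF core gave a ratio of 2.54, ETS 1.67, E-box 1.21, NF-kB 1.21 and the glucocorticoid and androgen receptor palindrome 1.21. Against flanks, ratios were small for the forkhead site (12.6% against 11.6%, 1.09, adjusted exact McNemar p = 0.000417) and the GATA site (1.17), and the RUNX site showed no detectable difference (1.005, adjusted exact McNemar p = 0.845). Among peaks at or above the median score ETS, E-box, NF-kB and the rearranged palindrome no longer passed (adjusted exact McNemar p from 0.0887 to 0.237), nor did forkhead (0.0541) and the glucocorticoid and androgen receptor palindrome (0.0559) in the central 200 bp. The CCAAT box was less frequent in peaks (35.5% against 43.7%, 0.812). Against shuffled peak sequences, the ratios of the rearranged palindrome, RUNX, ETS and NF-kB fell below 1 (0.799, 0.862, 0.821 and 0.665), and AP-2 and the palindromes with spacers of 2 and 4 bases fell to 1.13, 1.19 and 1.18. Against the same background the forkhead site rose to 2.57 (2.40 to 2.77) and the E-box to 1.98, GATA gave 1.62 and the ERE 8.31.

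**Figure D3:**
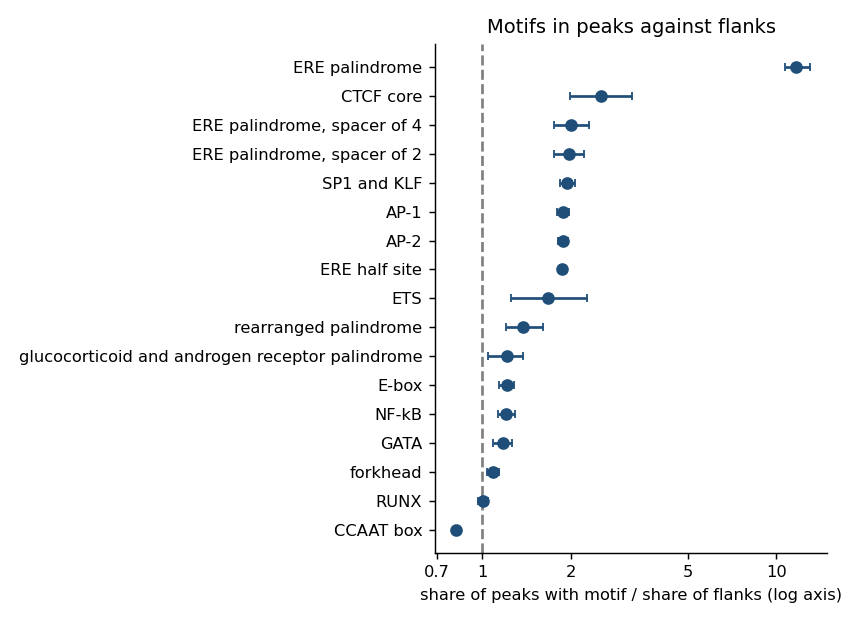
Ratio of the share of peaks with each motif to that of their flanks (horizontal log axis), with 95% bootstrap intervals, for the ERE, its control palindromes and other sites. The ERE at 11.7 stands apart from all others, which lie between 0.812 and 2.54.

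Peaks with higher scores carried the ERE more often. It was present in 33.2% of the 20% of peaks with the highest scores and in 5.07% of the 20% with the lowest, a ratio of 6.54 (Fisher's exact test, two-sided p = 3.60e-221). For exact matches this ratio was 14.7, and with 2 mismatches it was 2.77. Across peaks, which are not independent replicates, Spearman's rho was 0.270 (permutation p = 1e-05, the smallest that 100000 permutations can give). Score and width rose together (rho 0.631 across peaks), and a longer sequence has more chances of a match. Among peaks of similar width the ratio was 3.70 to 5.41.

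**Figure D4:**
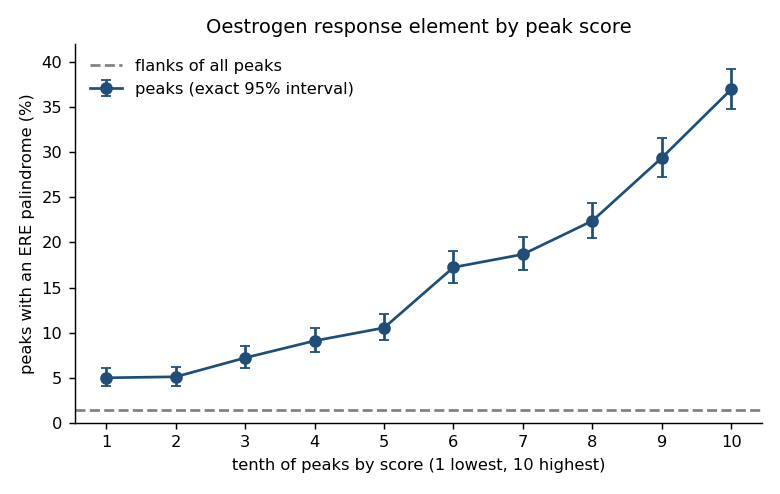
Share of peaks with an ERE (percent, vertical axis) in 10 equal groups of peaks ordered by score (horizontal axis), with exact 95% binomial intervals and the share of the flanks (1.38%) as a dashed line. The share runs from 4.99% in the lowest group to 37.0% in the highest.

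ERα peaks were mostly far from promoters. Of the peaks, 23.5% lay over 100 kb from a protein-coding TSS, the median distance was 30.7 kb, and 52.6% were in introns and 33.5% in intergenic sequence. Promoters still held more than random placement, with 1137 peaks (6.30%) within 1 kb against 2.83% (ratio 2.23). Within 5 kb there were 2908 peaks (16.1%) against 11.2% (95% range 10.8 to 11.7), a ratio of 1.44. Coding exons (1.87%, ratio 1.74) and other exons (4.20%, ratio 1.64) also exceeded random placement, and introns (ratio 0.942) and intergenic sequence (0.928) held less. The 3′ UTR share (1.36%) and the 5′ UTR count of 19 peaks were within the range of random placement.

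Peaks occurred in groups, as around TFF1, PREX1 and PAK4. The 1 Mb window with PREX1 (chromosome 20, 47000001 to 48000000), chosen after its values were seen, held 52 peaks. Their median width was 852.5 bp against 377 bp in the full list, 6 were wider than 2 kb and 9.6% held an ERE. Another peak began within 10 kb of 6497 peaks (36.0%), against 13.1% in random placements (95% range 12.4 to 13.7), a ratio of 2.75. The ratio was 4.95 among peaks at or above the median score, 2.86 without 17q and 20q, and 1.38 with a distance of 50 kb.

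The genome held 6.31 peaks per Mb, and chromosomes differed. Per Mb without N, chromosome 22 was the densest at 13.5 (exact 95% interval 12.3 to 14.8, ratio to the genome 2.14, adjusted exact binomial p = 1.28e-48). Chromosomes 20 (11 per Mb, ratio 1.75), 17 (10.7, ratio 1.70), 16 (10.3, ratio 1.63) and 19 (10.3, ratio 1.63) followed. Chromosome X had 2.22 per Mb (1.99 to 2.47, ratio 0.352, adjusted exact binomial p = 2.46e-121), and chromosomes 13 (3.71) and 4 (4.12) were also low. On chromosome 20 the long arm held 16 per Mb and the short arm 4.68. Of the 157 peaks wider than 2 kb, 63 were on 20q and 22 on 17q. Chromosome Y had 105 peaks (ratio 0.724, adjusted exact binomial p = 0.000712), of which 77 held tandem CATTC repeats. Its ratio was 0.303 with whole chromosome lengths and 0.259 with peaks closer than 10 kb merged, below that of X in both cases (0.371 and 0.401). With whole lengths chromosomes 20 (1.79), 17 (1.76) and 19 (1.67) ranked above chromosome 22 (1.58).

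**Figure D5:**
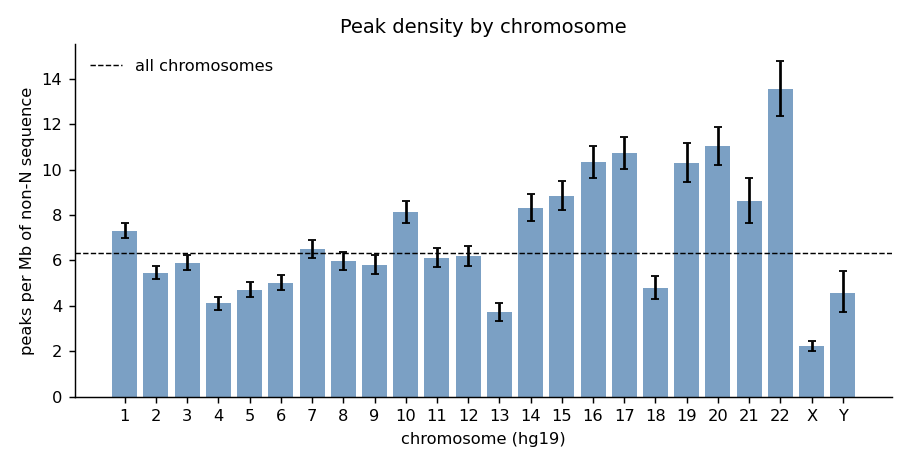
ERα peaks per Mb of sequence without N for each chromosome, with exact 95% binomial intervals and the genome mean of 6.31 as a line. Per Mb without N, chromosome 22 (13.5) is the highest and chromosome X (2.22) the lowest, ranks that change with whole chromosome lengths.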

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

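The CATTC test was chosen after the result was seen.

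Peaks on sequences outside the assembled chromosomes entered no comparison of the report. There were 141 on unplaced or unlocalised sequences, with a median score of 86.0 and a highest score of 1542. A further 55 were on alternative haplotype sequences, with a median score of 66.8 and a highest score of 1746. The median score on the assembled chromosomes was 80.1.

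Chromosome Y held 105 peaks with a median score of 75.2, 101 of them intergenic. The ERE was in 4 of them, 0.236 times the autosomal share (95% interval 0.0648 to 0.585), which argues against binding at receptor elements as the source of these peaks as a group. Tandem CATTC units were in 77 (73.3%), 72.1 times the autosomal share (60.8 to 86.9), so reads of satellite repeats are a candidate source. Such units were also in 179 autosomal peaks (1.02%), among them 47 on chromosome 4, 40 on chromosome 21 and 36 on chromosome 10. Copies on other chromosomes were 2.78 times as frequent as for autosomal peaks (1.054 to 4.84), an interval too wide to decide, and the alignment can miss satellites; no biological explanation from the design was tested.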

How the results depend on the processing

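The alternatives without 17q and 20q, without peaks wider than 2 kb and without repeated or Y peaks were chosen after the data were seen. Of 444 comparisons, 410 counted as the same, 15 as weaker, 10 as stronger, 4 as moved and 5 as reversed. These include the presence of a peak near 67 named genes, within 100 kb and with peaks at or above the median score. A gene with a peak within 50 kb has one within 100 kb by construction. Most of the checks of named genes at 100 kb could therefore only count as the same, which raises the count of 410. A ratio that crossed 1 counted as reversed only where either result passed its threshold. Chromosome 11 thus counted as the same, though its density ratio went from 0.969 to 1.034 with peaks at or above the median score. Peak counts and widths were judged by size and had no direction. The ratios of the ERE, of TSS proximity, of clustering and of the oestrogen-induced list were past their thresholds in the same direction under every alternative run, but their sizes moved. The ERE ratio ran from 2.84 (2 mismatches) to 48.2 (exact matches), TSS proximity from 1.28 (20 kb) to 2.23 (1 kb), clustering from 1.38 (50 kb) to 4.95 (peaks at or above the median score) and the oestrogen-induced list from 1.43 (100 kb) to 4.20 (10 kb). The luminal transcription factor list reached 3.25 with peaks at or above the median score and 3.87 within 10 kb. With peaks at or above the median score, 9020 peaks were left by construction, with a median width of 478 bp. The density ratio of chromosome 7 reversed to 0.877, chromosome 8 (0.876) passed the threshold and chromosome 9 (0.955) no longer did. The 5′ UTR (2.16) and the luminal epithelial list (2.21) passed, and the rearranged palindrome (1.33), ETS (1.45), E-box (1.11) and NF-kB (1.102) did not. PGR and CXCL12 had 0 peaks. The median width was 646 bp in the 10% of peaks with the highest scores and 373 bp without 17q and 20q. With whole chromosome lengths, chromosomes 3 (0.997) and 21 (1.08) no longer passed and chromosome 7 (1.09) did. With peaks closer than 10 kb merged, chromosomes 3 (0.948), 9 (0.970) and 21 (1.11) no longer passed and chromosome 7 (1.09) did. Against shuffled sequences, the rearranged palindrome (0.799), RUNX (0.862), ETS (0.821) and NF-kB (0.665) reversed. In the central 200 bp, the glucocorticoid and androgen receptor palindrome (1.31) and forkhead (1.095) no longer passed. Luminal transcription factors no longer passed with a window of 100 kb (1.41), where MYBL1 had 4 peaks and PAK6 had 2. Within 10 kb, the luminal epithelial (2.72) and immediate early (2.80) lists passed, the latter also with the gene body and 10 kb (2.93). Apart from the smaller number of peaks, the cause was not tested. The search without soft-masked bases was not run, because the reference had 0 such bases. With 1 library and unknown read depth, neither the spread between cultures nor the number of weak sites missed could be measured.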

Other observations

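The broad-peak test was chosen after the result was seen, as were the values per arm, the ERE shares of wide peaks and their flanks, and the motif and window summaries of the next paragraphs.

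Against flanks, forkhead and GATA sites, the sites of FOXA1 and GATA3, were enriched in high-scoring peaks and depleted in low-scoring ones. In the 10% of peaks with the highest scores the forkhead site was in 22.6% against 16.1% of flanks (ratio 1.40, 95% bootstrap interval 1.25 to 1.58), and in the 10% with the lowest scores the ratio was 0.692 (0.555 to 0.840). For GATA the ratios were 1.42 (1.197 to 1.67) and 0.753 (0.544 to 0.992). The difference between both groups of peaks was not tested, and no shuffled background was used for them. From the lowest to the highest group, the ratios of RUNX (0.825 to 1.07) and the CCAAT box (0.661 to 0.944) also rose. Those of AP-2 (2.22 to 1.81) and NF-kB (1.73 to 0.972) fell. The shift can therefore not be assigned to FOXA1 or GATA3. At promoters, within 1 kb of a TSS, the SP1 and KLF site was in 40% of peaks against 6.92% of flanks (ratio 5.78), compared with a ratio of 1.53 farther away. ETS (4.89), AP-2 (2.86) and E-box (2.01) sites also had ratios above 1 at promoters. The flanks began 2 kb outside each peak and were not chosen at promoters. These ratios therefore cannot separate receptor binding from promoter sequence. The ERE was enriched in both places, with ratios of 8.53 at promoters and 12 elsewhere.

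Some peaks and regions stood apart, chosen after their values were seen. At least 2 EREs were found in 115 peaks, whose median score was 421, against 167 for peaks with 1 and 72.8 for peaks with none. These groups were not matched on width, and wider peaks have both higher scores and more chances of a match. An intronic peak on chromosome 19 (197926 to 200538, 2613 bp wide), nearest to PLPP2, held 40 EREs. One near YBEY on chromosome 21 (47712276 to 47714890, 2615 bp wide, score 3100) held 29. The densest window of 1 Mb was on chromosome 20 from 46000001 to 47000000, with SULF2 and NCOA3, where 69 peaks had a median score of 74.1, 17 were wider than 2 kb and 5.80% held an ERE. The next were on chromosome Y from 13000001 to 14000000 (62 peaks, 54 with tandem CATTC units) and on chromosome 4 from 49000001 to 50000000 (59 peaks, 47 with such units), both without an ERE. The window with CYP19A1 (chromosome 15, 51000001 to 52000000) held 49 peaks, 4 of them wider than 2 kb. Their median width was 809 bp, their median score was 67.2 and 4.08% held an ERE. The window with TFF1, TFF2 and TFF3 (chromosome 21, 43000001 to 44000000) held 38 peaks, with a median width of 520 bp, a median score of 141.5 and an ERE in 13.2%.

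Peak density differed between chromosomes and went with the number of genes, since across the 22 autosomes Spearman's rho of peak density with gene density was 0.825 (permutation p = 3e-05), and Pearson's r was 0.664 (permutation p = 0.00094) and 0.810 without chromosomes 17 and 19. The arms 1q, 17q and 20q, commonly gained in MCF7, had 1.68 times the pooled density of the others (1.61 to 1.76), but they also held more genes (11.4 against 6.77 per Mb). Their density ratios were 1.27, 1.89 and 2.65. Their peaks per gene were 0.9 (0.837 to 0.966), 0.845 (0.780 to 0.915) and 1.66 (1.52 to 1.804) times those of the other arms. Peaks per gene thus exceeded those of the other arms on 20q alone of the 3. Dividing by genes assumes that peaks rise in proportion to genes, which was not tested, so gene content is not shown to account for 1q or 17q. Extra copies and gene content cannot be told apart, since copy number was not measured here, and no biological explanation from the design was tested. Peaks wider than 2 kb lay on 17q or 20q 8.94 times as often as narrower ones (7.61 to 10.4) but on 1q 0.285 times as often. Since 17q and 20q were picked from these counts, read depth of amplified blocks stays open as the source of these wide peaks. An ERE was in 14.5% of the wide peaks on 17q and 20q against 13.3% of their flanks (ratio 1.09, 0.5 to 2.11). In wide peaks on other arms it was in 15.5% against 4.2% of flanks (ratio 3.67, 1.43 to 14). Peaks of up to 2 kb on 17q or 20q had a ratio of 7.72 (5.71 to 11.1).

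Most peaks (83.8%) held no ERE with at most 1 mismatch. Background calls may be part of this, since the share with an ERE was 7.49 times higher in the 10% of peaks with the highest scores than in the 10% with the lowest (6.16 to 9.31), but 63.0% of the former lacked it too and the latter still exceeded their flanks 5.56 times (3.79 to 9.0). Peaks within 1 kb of a TSS held the ERE 1.048 times as often as others (0.914 to 1.199), though against flanks its ratio was 8.53 there and 12 elsewhere. Of the peaks without an ERE, 6.25% lay within 1 kb of a TSS, which argues against open promoters as the main source. Binding through other factors stays open, since at matched width AP-1 sites were 1.32 times (1.198 to 1.46) as frequent in peaks without an ERE, SP1 and KLF sites 1.24 times and forkhead sites 1.13 times. No biological explanation from the design was tested, and weaker EREs are not excluded, as 76.3% of the peaks with the highest scores had a match with 2 mismatches, against 27.2% of their flanks (ratio 2.80).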
